A study of Homo sapiens with 6 samples.

How the data were processed

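The data are 6 Illumina bead arrays of KG1a cells, 3 of control cells and 3 of cells given 7l at 2 µM for 24 h. Groups and replicate numbers were taken from the sample titles, since the description field carries 1 replicate number per group, and every column of the table was mapped to a sample by its name. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on columns with DNase treatment and made into biotinylated cRNA. The control's vehicle and time in culture and the identity of 7l are not given in the sources used here. The authors deposited 1 table of probe intensity on a linear scale. The background correction, normalization and software behind it are not given in the sources used here. The deposited intensity values themselves run from 1 to 10984, and the sorted values of the 6 arrays are equal at 97.8% of ranks (within 0.0001 of their size), as quantile normalization leaves them. Quantile normalization forces the arrays to 1 distribution, so a global rise or fall of all transcripts cannot be seen. At the floor of 1, 4703 probes sat on all 6 arrays, and fold changes against such values depend on the floor. No detection p-values were used here.

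Probes were named through a platform table. Of 47322 probes, 30113 carry 1 gene symbol, 8 carry several and 17201 are unnamed in that table. Genes were named only from probes with 1 symbol, which name 20046 genes. The gene numbers of 30074 probes were found in a RefSeq gene table, and 0 symbols changed. No coordinates are given, and positions in the gene table served only to find the host genes of snoRNA genes.

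Values were set to at least 1 and log2 transformed, with no further normalization because the array medians did not differ by over 0.1. For each gene the probe with the highest mean over the 6 arrays was kept, and genes were tested if this mean exceeded the median of all probe means (log2 1.76), which left 12334 genes. The fit used R 4.3.3 and limma 3.58.1, with lmFit and eBayes (default prior, two-sided, group as the only term), 4 residual degrees of freedom, a prior of 1.24 degrees of freedom and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and changes are 7l minus control. The low prior degrees of freedom mean that the fit borrowed little between genes. Of 91 called genes with another probe above the filter, 84 had every such probe of the same sign.

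The level of unexpressed genes was taken as the 95th percentile of the means of 562 probes for olfactory receptors, taste receptors and keratin-associated proteins (log2 2.46, intensity 5.49). It is an estimate, since some of these genes can be expressed. A group whose 3 arrays all lay at or under this level has only a bound, and its fold is given as at least the bright group's mean over the dim group's values raised to that level.

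In total 37 gene lists and 12 lists of cell type markers were fixed, and 48 with at least 5 tested genes entered camera with a preset correlation of 0.01. Their results are each printed once, and 5 of the 15 calls held with a correlation estimated from the data. The genes named are the 12 highest and 12 lowest called genes whose groups do not overlap, up to 4 members of each list past the threshold, up to 2 of other lists and a panel of 16 genes. Genes named outside this rule are said to be named after their values were seen. Genes on chromosome Y were left out of the text. The lists, the rule, the test and the main alternatives were fixed before the data were examined. The alternatives were other normalizations, filters, ways to combine probes, priors, array weights, an offset of 16, the replicate number as a block, each array left out and other list tests.

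The gene test was checked on a single simulated data set made from the 12334 genes of this comparison. In it 200 genes were changed by known amounts, and further genes were raised or lowered by 0.5 to check the list test. Among the 200, the gene test called 4% of genes changed by 0.5 on the log2 scale and 68% of those changed by 1. It called 72% of those changed by 2 and 88% of those changed by 3. Of 133 genes called there, 14 were unchanged, and 0 of the called genes among the 200 had the wrong sign. Small changes were mostly missed, and the share of unchanged genes among calls was above the nominal level in this simulation. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.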

Results

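Gene expression was measured in KG1a cells, a human acute myeloid leukaemia line of immature, CD34-bearing cells, on 6 Illumina expression arrays. Cells of the treated group had been given 7l, an agent known here only by this code name, at 2 µM for 24 h, and 3 arrays of treated cells were set against 3 arrays of control cells. Each array gave values for 47322 probes. The median intensity was 4.95 on every array, between 32.7% and 34.2% of the probes of an array sat at the lowest value of 1, and 22815 probes of each array lay above the level of genes that blood cells do not use. The number of arrays limits the precision of every value below. The titles number the arrays of each group 1 to 3, but the description field gives all control arrays as replicate 1 and all treated arrays as replicate 2. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Over probes with a mean log2 intensity above 6, arrays of the same group correlated at 0.993 to 0.995 and arrays of different groups at 0.982 to 0.983 (Pearson, across probes, which are not independent replicates).

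The comparison asked which transcripts differed between KG1a cells given 7l and control cells. With 7l, genes of the antioxidant response driven by NRF2 rose most as a group, with NQO1 (a quinone reductase) 5.75-fold and SRXN1 (sulfiredoxin) 3.95-fold higher. Genes of mitosis and of the amino acid response driven by ATF4 also rose, whereas interferon-induced genes and genes of DNA replication fell. Of 12334 genes tested with limma, 150 were higher and 143 lower with 7l at an adjusted p under 0.05, of which 51 and 38 differed at least 2-fold. In all 293 called genes the 3 treated arrays lay beyond all 3 control arrays. This was so for 28.9% of all genes tested, where chance gives 10%. The median size of a called change was 0.75 on the log2 scale. The gene counts needed all 6 arrays under the default prior: without any 1 array, 6 to 15 genes were called higher and 0 to 18 lower, whereas 7 to 8 of the lists called higher and 6 to 7 of those called lower kept their call. With a trended and robust prior the full set of arrays gave 889 higher and 813 lower genes.

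**Figure D1:**
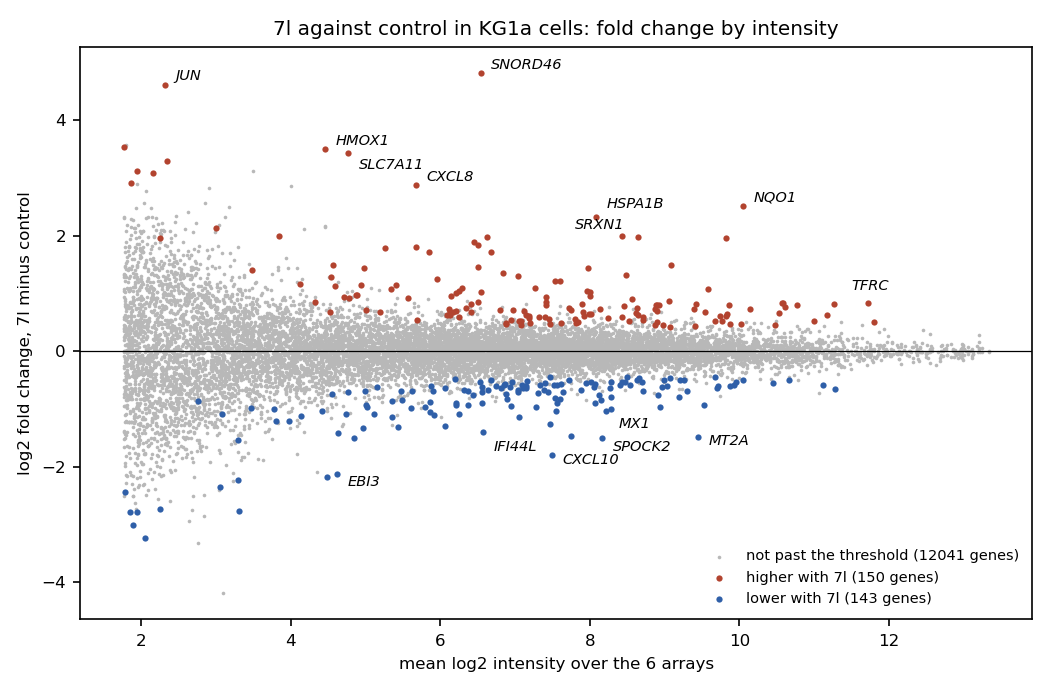
Log2 fold change (7l minus control) of each tested gene against its mean log2 intensity over the 6 arrays, with the 150 genes called higher in red, the 143 called lower in blue and the rest in grey. Dim genes scatter most.

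Of the 19 tested genes of the NRF2 oxidative stress list, 11 rose, 0 fell and 8 did not pass (16 higher and 0 lower when adjusted over the list alone). NQO1 went from 8.79 ± 0.02 in control cells to 11.31 ± 0.05 in treated cells (mean log2 intensity ± SD, n = 3 each), a change of 2.52 ± 0.06 (SE; limma adjusted p = 0.000685). SRXN1 rose by 1.98 ± 0.07 (adjusted p = 0.00295), TXNRD1, a thioredoxin reductase, by 1.49 ± 0.10 (adjusted p = 0.0123) and PIR, encoding pirin, by 0.91 ± 0.07 (adjusted p = 0.0157). HMOX1, encoding heme oxygenase 1, rose by 3.50 ± 0.33 (adjusted p = 0.0223) and SLC7A11, the cystine transporter subunit, by 3.44 ± 0.45 (adjusted p = 0.0359). With an offset of 16, which shrinks folds of dim genes, these were 1.98 and 2.09. The list as a whole was higher than other genes, with a median log2 change of 0.81 (camera adjusted p = 2.39e-14), and its call held with an estimated correlation (adjusted p = 0.0357).

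The ATF4 and amino acid list shares SLC7A11 with the NRF2 list. Of its 20 tested genes 7 rose, 0 fell and 13 did not pass (14 higher and 1 lower adjusted over the list alone). PSAT1, an enzyme of serine synthesis, rose 1.73-fold (log2 0.79 ± 0.06, adjusted p = 0.0175 by limma). SLC3A2 and SLC7A5, which form a transporter of large neutral amino acids, rose by 1.08 ± 0.09 and 0.76 ± 0.08, and ASNS, asparagine synthetase, by 0.75 ± 0.10 on the log2 scale. Its median was 0.49 (camera adjusted p = 2.61e-10, and adjusted p = 0.0304 with an estimated correlation). DDIT3, a further stress gene of the list, measured 1.07 ± 0.44 (0.42 with an offset of 16) and did not pass (adjusted p = 0.264). No gene of the 17 tested in the unfolded protein response list passed, also when adjusted over the list alone, and its median was 0.01 (camera adjusted p = 0.771). DNAJB9 and EDEM1 had the smallest p-values in it, at 0.54 ± 0.15 and 0.31 ± 0.10. The 18 tRNA synthetase genes held no called gene (1 higher adjusted over the list alone, AARS1 at 0.38 ± 0.06), with a median of 0.09 (camera adjusted p = 0.276).

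In the cholesterol and SREBP2 list 4 of 18 tested genes rose, 0 fell and 14 did not pass (14 higher and 0 lower adjusted over the list alone). HMGCS1, which makes the precursor of mevalonate, rose 1.74-fold (log2 0.80 ± 0.09, limma adjusted p = 0.0266), MSMO1 1.92-fold, SC5D 1.73-fold and INSIG1 1.45-fold. The first 3 encode enzymes of sterol synthesis and the last a regulator of it. Over all 18 genes the median was 0.40 (camera adjusted p = 1.33e-08, but adjusted p = 0.0670 with an estimated correlation). Of 13 genes in the fatty acid and SREBP1 list 3 rose (also 3 adjusted over the list alone): the desaturase genes FADS2 (1.90-fold), FADS1 (1.66-fold) and SCD (1.38-fold). ME1, encoding malic enzyme, had a control mean under the background level, and with values raised to that level its log2 change was 1.65. It did not pass (adjusted p = 0.147). This list's median was 0.20 (camera adjusted p = 0.0313, but adjusted p = 0.338 with an estimated correlation).

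In the autophagy and lysosome list 5 of 25 tested genes rose and 0 fell (9 and 0 adjusted over the list alone), among them the lysosomal enzyme genes NEU1 (1.81-fold) and GLA (1.75-fold), the autophagy receptor gene SQSTM1 (1.67-fold) and MAP1LC3B (1.54-fold), whose product coats autophagosomes. The fifth, NPC1, a lysosomal cholesterol transporter, rose 1.52-fold and is named after its value was seen. The list's median was 0.31 (camera adjusted p = 4.61e-05, but adjusted p = 0.140 with an estimated correlation), and SQSTM1 also counts in the NRF2 list. In the heat shock list 4 of 17 tested genes rose and 0 fell (5 and 0 adjusted over the list alone). HSPA1B, an inducible HSP70 gene, rose 5.04-fold (log2 2.33 ± 0.15, limma adjusted p = 0.0121), the co-chaperone genes BAG3 and DNAJB1 2.15-fold and 1.67-fold, and HSPH1 1.57-fold. HSPA1A, a near-identical copy of HSPA1B, lay under the intensity filter at 0.00 ± 0.00 in control and 0.66 ± 0.65 in treated cells (mean log2 ± SD, n = 3 each), so signal shared between the 2 copies leaves the source of the HSPA1B value uncertain. The median of the heat shock list was 0.14 (camera adjusted p = 0.0148, but adjusted p = 0.207 with an estimated correlation).

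**Figure D2:**
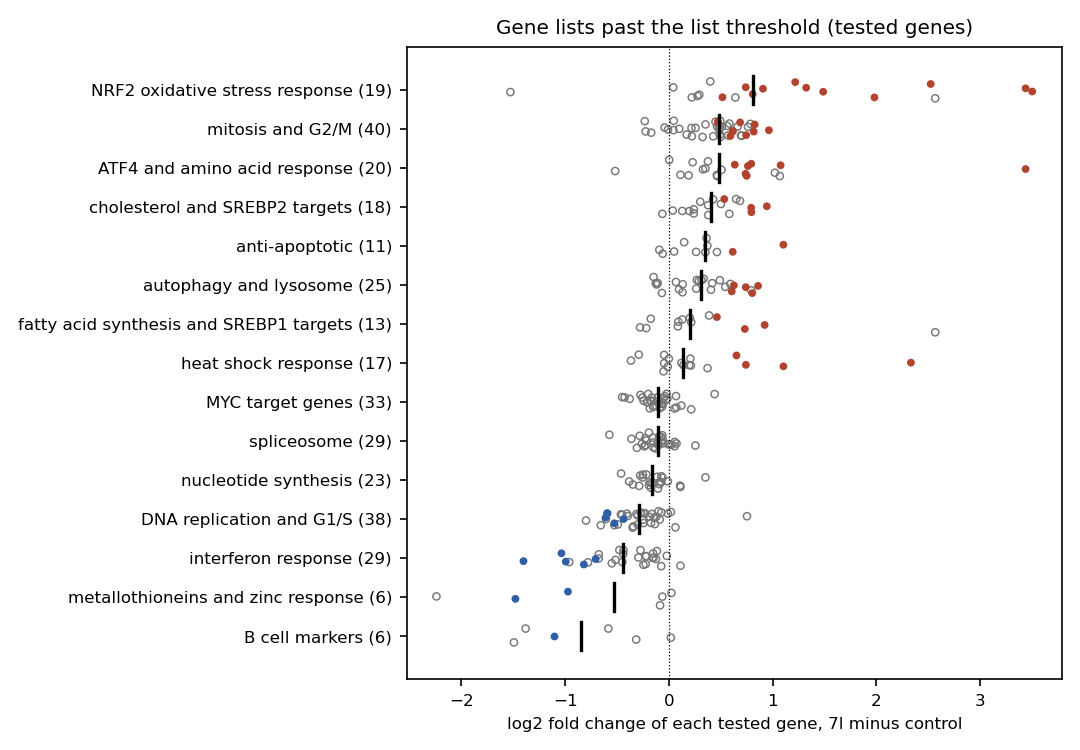
Log2 fold change (7l minus control, horizontal axis) of each tested gene in the 15 lists past the list threshold, with the number tested in brackets, called genes filled (red higher, blue lower), other genes as open circles and the median as a black bar. The NRF2 list has the highest median, 0.81, and the B cell list the lowest, -0.85.

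The cell cycle genes divided by phase. In the mitosis and G2/M list 9 of 40 tested genes rose, 0 fell and 31 did not pass (27 higher and 2 lower adjusted over the list alone). CDC20, an activator of the anaphase-promoting complex, rose 1.77-fold (log2 0.83 ± 0.07, limma adjusted p = 0.0216), CDCA8 and BIRC5, both of the chromosomal passenger complex, 1.68-fold and 1.53-fold, and CENPA, the centromeric histone, 1.53-fold. The mitosis list had a median of 0.49 (camera adjusted p = 3.18e-13, and adjusted p = 0.0444 with an estimated correlation). In the DNA replication and G1/S list 0 of 38 tested genes rose, 5 fell and 33 did not pass (0 higher and 14 lower adjusted over the list alone). MCM7 and MCM5, subunits of the replicative helicase, were 1.51-fold lower each (log2 -0.60 ± 0.07 and -0.59 ± 0.09), CCNE1, cyclin E1, 1.53-fold and GINS2 1.44-fold lower. Another CCNE1 probe had the opposite sign, and with all probes of a gene averaged CCNE1 measured -0.18 and did not pass (adjusted p = 0.739). PCNA, the sliding clamp, fell 1.35-fold and is named after its value was seen. The replication list had a median of -0.29 (camera adjusted p = 3.13e-11, and adjusted p = 0.0304 with an estimated correlation). MKI67, a proliferation marker, measured 0.10 ± 0.13 and did not pass. CDKN1A, which encodes the CDK inhibitor p21, rose 2.06-fold (log2 1.04 ± 0.06, limma adjusted p = 0.0117). It was the 1 called gene of 11 in the list of CDK inhibitors and D cyclins (3 higher and 1 lower adjusted over the list alone), whose median was 0.09 (camera adjusted p = 0.256). CCND2 measured -0.24 ± 0.07 and did not pass.

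Genes of the interferon response fell. Of 29 tested, 0 rose, 5 fell and 24 did not pass (0 higher and 15 lower adjusted over the list alone), and 28 of the 29 had a negative log2 change. IFI44L was 2.64-fold lower (log2 -1.40 ± 0.08, limma adjusted p = 0.0108), the antiviral GTPase gene MX1 2.05-fold, the immunoproteasome gene PSMB9 1.99-fold and the oligoadenylate synthetase gene OAS3 1.63-fold lower. OAS2, named after its value was seen, was 1.77-fold lower. The list's median was -0.44 (camera adjusted p = 3.13e-11, and adjusted p = 0.0304 with an estimated correlation). The interferon-inducible chemokine gene CXCL10 was 3.48-fold lower (log2 -1.80 ± 0.12, adjusted p = 0.0121). It counts in the NF-kappaB list, where members went both ways. Of its 22 tested genes 2 rose and 3 fell (2 and 4 adjusted over the list alone). The neutrophil chemokine gene CXCL8 rose 7.39-fold (log2 2.88, or 2.16 with an offset of 16) and PTGS2, cyclooxygenase 2, 2.13-fold, whereas EBI3 was 4.34-fold (log2 -2.12, or -1.27 with an offset of 16) and SOD2, mitochondrial superoxide dismutase, 1.52-fold lower beside CXCL10. PTGS2 and SOD2 are named after their values were seen. The NF-kappaB list's median was -0.11 (camera adjusted p = 0.0912), and NFKBIA, an inhibitor of NF-kappaB, measured -0.34 ± 0.11 and did not pass.

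**Figure D3:**
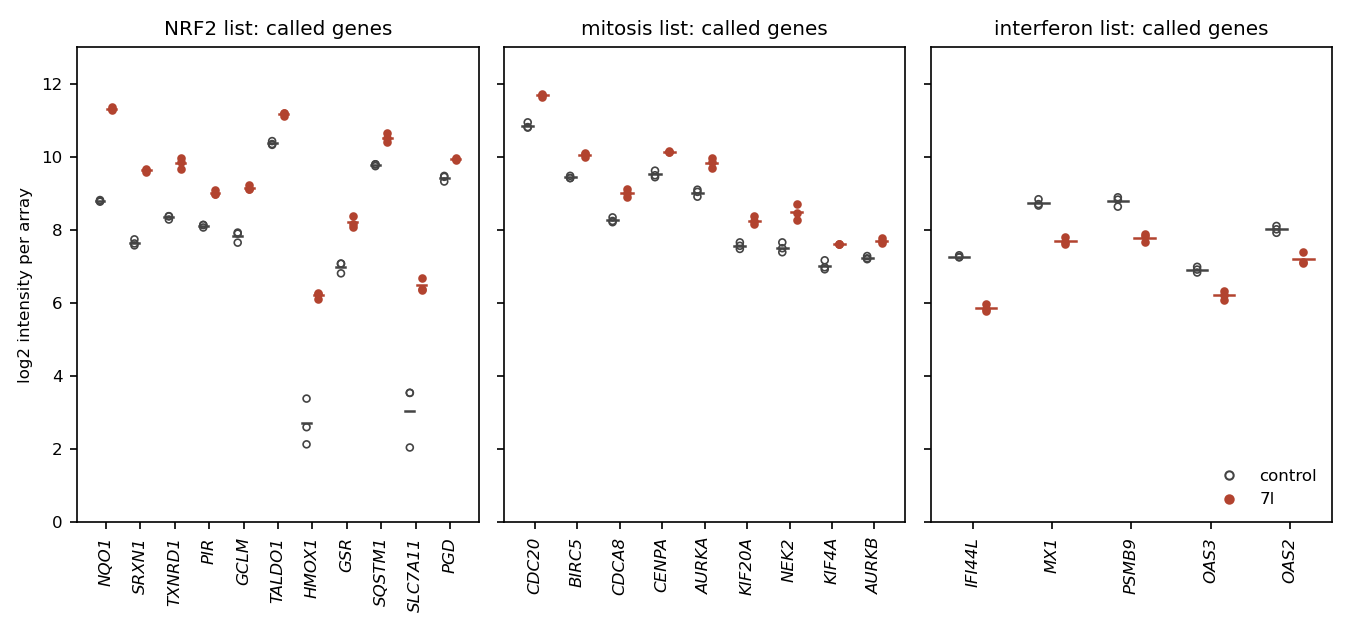
Log2 intensity on each array (3 control, open circles, and 3 treated with 7l, filled circles; bars are group means) of every called gene in the NRF2, mitosis and interferon lists, including members the text does not name. In each gene shown the treated arrays lie on 1 side of all control arrays.

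Of the 6 tested metallothionein and zinc genes 2 fell (3 adjusted over the list alone) and 0 rose. MT2A was 2.79-fold lower (log2 -1.48 ± 0.13, limma adjusted p = 0.0182) and MT1X 1.96-fold lower, both encoding metal-binding proteins of near-identical family members, so signal shared between them cannot be excluded. MT1G, with a treated mean under the background level, measured -1.64 with values raised to it and SLC30A1, a zinc exporter gene, -0.09 ± 0.09, and neither passed. The list's median was -0.53 (camera adjusted p = 0.00950, but adjusted p = 0.207 with an estimated correlation).

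The spliceosome, MYC target and nucleotide synthesis lists were called lower with no member past the gene threshold. None of the 3 calls held with an estimated correlation. Over all alternatives, some of which could hardly change the list test, the spliceosome and MYC target calls each held in 18 of 19. The nucleotide synthesis call held in 17 of 19. The spliceosome list had an adjusted p = 0.207 with an estimated correlation, the MYC targets an adjusted p = 0.151 with an estimated correlation and nucleotide synthesis an adjusted p = 0.338 with an estimated correlation. The 29 spliceosome genes had a median of -0.11 with 23 negative (HNRNPA1 -0.57 ± 0.11, PRPF3 -0.36 ± 0.10), the 33 MYC targets a median of -0.11 with 27 negative (NCL, nucleolin, -0.24 ± 0.07, ODC1 -0.20 ± 0.07), and the 23 nucleotide synthesis genes a median of -0.17 with 20 negative (MTHFD1 -0.46 ± 0.09, PFAS -0.35 ± 0.07). Each list had a camera adjusted p of 0.00950. Adjusted over the list alone, 0 spliceosome genes and 0 MYC targets passed, and 1 nucleotide gene was higher and 2 lower. MYC itself measured -0.18 ± 0.07 (limma adjusted p = 0.253).

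The highest and lowest genes outside these lists were varied, and many were dim. SNORD46, a small nucleolar RNA, was 28.3-fold higher (log2 4.82 ± 0.08, or 3.93 with an offset of 16, limma adjusted p = 0.000146). JUN, a subunit of AP-1, was not well above background on any control array and was at least 4.48-fold higher with 7l (adjusted p = 0.00296). By the same bound PRLR, the prolactin receptor, was at least 2.12-fold, TGM5 at least 2.89-fold, SNORA46 at least 2.07-fold, PRSS35 at least 2.37-fold and MSC at least 1.82-fold higher, and a second TGM5 probe had the opposite sign. All 3 control values of JUN and of PRLR sat at the floor with no spread, so the p-values of these genes depend on the floor. JUN was the 1 called gene of 24 in the list of immediate early and short-lived transcripts (5 higher adjusted over the list alone), with a median of 0.24 (camera adjusted p = 0.0846). Among lower genes, RGS1, a regulator of G protein signalling, was 4.52-fold lower (log2 -2.18, or -1.25 with an offset of 16). The treated means of CD247, the T cell receptor zeta chain, and MIR216A lay under the background level, and with treated values raised to that level they were 3.69-fold and 4.38-fold lower, a step added after their values were seen. PICK1 (at least 2.32-fold), TIGIT (at least 1.91-fold), SLC10A2 (at least 1.83-fold), C17orf78 (at least 1.71-fold), OR5AS1 (at least 2.22-fold), FBLN1 (at least 1.47-fold) and PDE9A (at least 3.40-fold lower) were not well above background on any treated array. OR5AS1 is itself an olfactory receptor gene, of a family used to set the background level. Its control arrays still lay above that level, at 3.37 to 3.74 (log2), so bounds of like size for other dim genes are uncertain too. In all, 16 called genes had 1 group at background, and no order is read among their values.

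In the anti-apoptotic list 2 of 11 tested genes rose and 0 fell (4 and 0 adjusted over the list alone), BAG3 and BIRC5, which also belong to the heat shock and mitosis lists. Its median was 0.35 (camera adjusted p = 0.00590, but adjusted p = 0.169 with an estimated correlation). BCL2 measured 0.26 ± 0.07 and MCL1 0.37 ± 0.16, and neither passed. Of 21 pro-apoptotic genes PMAIP1, encoding NOXA, rose 2.34-fold (log2 1.22 ± 0.11, limma adjusted p = 0.0205) and the others did not pass (3 higher adjusted over the list alone), with a list median of 0.14 (camera adjusted p = 0.186). In the p53 target list CDKN1A rose and TP53I3 was 2.51-fold lower among 19 genes (2 higher and 1 lower adjusted over the list alone). With all probes of a gene averaged TP53I3 measured -0.29 and did not pass (limma adjusted p = 0.790). The p53 list's median was 0.12 and its mean -0.00, so they differ in sign (camera adjusted p = 0.628). The 24 DNA repair and checkpoint genes held no called gene, also when adjusted over the list alone, with a median of -0.07 (camera adjusted p = 0.186).

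Of the lists of blood lineage markers only that of B cells passed, but with an adjusted p = 0.315 with an estimated correlation. CD34 measured -0.23 ± 0.08 and CD38 -0.37 ± 0.20, and neither passed. Of 16 stem and progenitor genes MYB fell 1.41-fold (1 lower adjusted over the list alone), with a median of 0.07 against a negative direction in camera (adjusted p = 0.838). The B cell list had a median of -0.85, or -0.57 with values raised to the background level (camera adjusted p = 0.0201, but adjusted p = 0.315 with an estimated correlation), with IGLL1, a surrogate light chain, 2.16-fold lower and the other 5 genes not past the threshold (2 lower adjusted over the list alone). CD79B measured -0.58 ± 0.09 with both its other probes of opposite sign. CD22 and MS4A1 had treated means under the background level, and with values raised to it measured -0.84 and -0.56. The megakaryocyte list had 2 of 8 genes lower, NFE2 1.62-fold and ITGA2B 1.45-fold (2 adjusted over the list alone; median -0.11, or 0.01 with raised values, camera adjusted p = 0.396). GFI1, a granulocytic repressor, was 1.63-fold lower among 13 granulocyte genes (2 higher and 2 lower adjusted over the list alone; median -0.38, or -0.15 with raised values, camera adjusted p = 0.467). TFRC, the transferrin receptor, rose 1.79-fold among 5 erythroid genes (1 adjusted over the list alone; median -0.17, camera adjusted p = 0.933). CD3D was 1.58-fold lower among 7 T cell genes (1 adjusted over the list alone; median -0.04, camera adjusted p = 0.186). No gene of the monocyte (10 genes, median -0.26, camera adjusted p = 0.379), NK cell (9 genes, median -0.23, camera adjusted p = 0.335) or dendritic cell list (6 genes, median 0.76, or 0.43 with raised values, camera adjusted p = 0.186) was called. Adjusted over the list alone, 1 monocyte gene was lower and 0 NK or dendritic genes passed. CD14 measured 0.75 ± 0.29. The 7 mast cell, basophil and eosinophil genes held no call (1 higher and 2 lower adjusted over the list alone), with a median of 0.05, or -0.00 with raised values, against a negative direction in camera (adjusted p = 0.628). FBLN1 was the 1 called gene of 5 fibroblast genes (1 lower adjusted over the list alone; median -0.33, camera adjusted p = 0.186), and with 3 tested genes the epithelial list was too small for a list test (median -0.33, or -0.16 with raised values, 0 called, also adjusted over the list alone).

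Signalling and drug-response lists did not pass. The FOXO and PI3K list had 1 higher gene of 17, the mTOR inhibitor DDIT4 (1.67-fold; 2 higher adjusted over the list alone; median 0.03, or 0.00 with 1 dim gene at its bound, camera adjusted p = 0.512). In the list of genes responsive to HDAC inhibitors 2 of 15 rose, CDKN1A and the histone gene H2BC12 (1.48-fold), and 2 fell, MT1X and MT2A (3 and 2 adjusted over the list alone). Its median was -0.14 and its mean 0.02, of opposite sign (camera adjusted p = 0.738). In the BET inhibitor list H2BC12 rose and MYB fell among 16 genes (3 and 2 adjusted over the list alone), with a median of -0.09 and a mean of 0.04, again of opposite sign (camera adjusted p = 0.771). No gene was called in the STAT3 and STAT5 (16 genes, PIM1 0.43 ± 0.08, median 0.10, camera adjusted p = 0.750), MAPK and ETS (14 genes, EGR1 0.75 ± 0.16, median 0.07, camera adjusted p = 0.535), Notch and Wnt (7 genes, NOTCH1 0.39 ± 0.08, median -0.14, camera adjusted p = 0.738) or nuclear receptor list (19 genes, TIPARP 0.50 ± 0.10, median 0.11, camera adjusted p = 0.738). Adjusted over the list alone, 1 STAT gene, 0 MAPK genes and 1 Notch or Wnt gene were higher, and 3 nuclear receptor targets were higher and 3 lower. FGFR1 lay under the intensity filter, at 1.67 ± 1.45 in control and 0.20 ± 0.34 in treated cells (mean log2 ± SD, n = 3 each).

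Of the metabolic and structural lists, glycolysis and hypoxia had 1 higher gene of 27, PKM, pyruvate kinase (1.77-fold; 1 adjusted over the list alone; median 0.04, camera adjusted p = 0.495), and histone genes 1 of 19, H2BC12 (1 adjusted over the list alone; median 0.12, camera adjusted p = 0.512). TXNIP, a glucose-responsive gene, measured -0.14 ± 0.15. No gene was called among 28 of oxidative phosphorylation (median -0.03, camera adjusted p = 0.256), 31 ribosomal protein genes (median -0.01, camera adjusted p = 0.628), 26 proteasome genes (median 0.03, camera adjusted p = 0.396), 25 of mitochondrial translation (median -0.02, camera adjusted p = 0.660), 23 of tubulin and the cytoskeleton (median 0.05, camera adjusted p = 0.535) or 12 of heme and globin synthesis (median 0.09, camera adjusted p = 0.628). Adjusted over the list alone, 1 mitochondrial translation gene, MRPS28 at -0.55 ± 0.09, passed, and 0 genes of the other 5 lists did.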

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

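Here the tests of unnamed probes, of fewer dividing cells and of ribosomal RNA were chosen after the result they bear on was seen. The comparison of small nucleolar RNA calls with matched lists was not stated beforehand either. The other tests' outcomes were stated beforehand, but the reading of the small nucleolar RNA median was refined after its value was seen. All patterns weighed were noticed in the same data. Further lists hold genes of the same kind on the same arrays, so they are not independent evidence. Bootstrap intervals resample genes, which can move together, and do not measure the spread between cultures.

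Of 7065 probes with no gene name and a mean above the filter, which the comparison of genes does not use, 17 were higher and 2 lower with 7l. They had a limma fit of their own, with its own prior and adjustment over these probes alone. The calls are 0.269% of them, against 2.38% of the named genes. These shares are not alike in threshold: all 17 and 2 differed at least 2-fold, against 51 and 38 of the 293 named genes called. Named genes also entered with their brightest probe only.

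Small nucleolar RNA (snoRNA) genes stood out among the highest calls. Of 158 tested, 15 were higher and 4 lower, yet 83 were positive and their median was only 0.02, inside the range of matched random lists (95% of them between -0.06 and 0.08), so the class as a whole was not higher. The median's percentile among 10000 random lists matched on intensity was 64.37, inside the range set beforehand as the mark of an intensity-dependent shift. With members going both ways it was read as deciding nothing. For the calls, 9.49% of snoRNA genes were called higher against 1.11% of other genes. Of the 10000 matched lists 0 held as many higher calls (median 1, highest 9). That argues against chance picks among genes of like intensity for these calls. The class was noticed for them, though, so the count is not an independent test. A like rise in the level of host transcripts is argued against for the 10 called snoRNA genes with a tested host. These hosts had a median of 0.02 (0.0221, 95% bootstrap interval -0.16 to 0.23) and 0 were called. The snoRNA genes, picked for their calls, had 1.78. The arrays measure transcript level rather than transcription, so a change in host transcription stays open. Other called snoRNA genes, SNORD46 among them, had no tested host. More carry-over of short RNA stays open, since its test cannot decide. The 19 other short RNA genes had a median of 0.30 (-0.06 to 0.42) with 0 called. The bar for them came from the median of all snoRNA genes and was only 0.01, which almost any rise reaches. The bar for hosts came from the called snoRNA genes and was 0.89, which the interval of the short RNA genes does not reach either. Ribosomal RNA genes went both ways. RNA28SN5, of the 28S ribosomal RNA, which is not short, rose by 0.84 (limma adjusted p = 0.0380). RNA5S9, of the short 5S ribosomal RNA, measured 0.72 (adjusted p = 0.0696) and RNA18SN5 -0.39 (adjusted p = 0.119).

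Mitosis genes rose while DNA replication genes fell. An intensity-dependent shift is argued against: the medians lay at percentiles 100 and 0 of the matched random lists, and although the prediction named the smaller distance from the nearer end and the test used the larger, both were 0 percentile points. In further lists that share no gene with these, 33 of 36 G2/M genes were positive (median 0.43, lower bound 0.36), which argues against fewer dividing cells as the whole cause. In them 27 of 33 G1/S genes were negative (median -0.22), a difference of medians of 0.64 (0.51 to 0.79 over resampled genes). Of these genes 7 of G2/M were called higher and 0 of G1/S were called. A larger share of cells in G2 or mitosis may be the cause, as a hypothesis. Cell cycle phase was not measured, and direct regulation of these genes stays open.

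Interferon response genes fell. An intensity-dependent shift is argued against, as the list's median lay at percentile 0 of the matched lists (95% of them between -0.09 and 0.11). In a further list of interferon-stimulated genes 25 of 30 were negative with a median of -0.21 (-0.32 to -0.13), and 1 was called lower. Lower interferon signalling in treated cells may be the cause, as a hypothesis. The description field gives every control array as replicate 1 and every treated array as replicate 2, and whether the groups were cultured or hybridised apart is not stated, so such a difference between the groups stays open for all 3 patterns.

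There are 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. The real split, 1 of 10 in each case, gave 150 higher and 143 lower genes (51 and 38 at least 2-fold) against 0 in every other split, and 8 higher and 7 lower lists against at most 2 in the other splits. Every other split mixes control and treated arrays, so a real difference adds to the spread within its groups. The low counts there thus do not show what chance alone would give.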

How the results depend on the processing

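Leaving out arrays under the trended prior, leaving out snoRNA genes and raising dim values to background were chosen after the result was seen. No named gene or list that passed changed direction under any alternative. Counts (150 higher and 143 lower, 51 and 38 at least 2-fold) moved with the variance prior and filter: 232 higher with no filter, 583 and 499 with a filter at the 70th percentile, 388 and 346 (31 and 14 at least 2-fold) with an offset of 16, and 889 and 813 (82 and 73) with a trended and robust prior, which included 147 and 135 of the main calls. The cause was not tested, except that the offset shrinks the folds of dim genes by construction. Array weights, the filter at background, mean probes, single probes and leaving out snoRNA genes (133 and 135) stayed within 1.5 times. Quantile and median normalization gave the main counts again, but they test little here, since the arrays already shared 1 distribution and 1 median. Without 1 array the counts were 6 to 15 higher and 0 to 18 lower, the same range at 2-fold: 9 and 0 without control replicate 1, 13 and 2 without control 2, 12 and 3 without control 3, 8 and 10 without 7l replicate 1, 15 and 18 without 7l 2, and 6 and 2 without 7l 3. Fewer arrays leave fewer degrees of freedom, and the cause was not tested further; 1986 to 2207 genes still had an unadjusted p under 0.05 in limma, and under the trended prior 635 to 822 were higher and 551 to 706 lower.

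With the replicate number as a replicate block, 0 genes were higher and 0 lower, also at 2-fold, where 2107 had an unadjusted limma p under 0.05; 7 lists were higher and 7 lower. The numbers do not pair the arrays: deviations of same-numbered arrays correlated at -0.02, -0.00 and 0.00, so arrays share only a number. For lists, 3 were higher and 2 lower with an estimated correlation, and 17 and 13 with fry, which does not compare a list with other genes; other settings gave 6 to 9 higher and 5 to 7 lower. The B cell call held in 14 of 18 alternatives and the fatty acid call in 14 of 19. These include both normalizations and the trended prior, which could hardly change the main list test. Of 1131 alternative values of the 72 named called genes, 642 stayed past the threshold and 489 did not. All 72 stayed with quantile and with median normalization, so those values add little to the 642. With the probes of a gene averaged, TP53I3, PSAT1, ASNS, MSMO1, INSIG1, MCM7, CCNE1, H2BC12, OAS3, MYB, IGLL1 and CD3D did not pass. Values near the background level limit what dim genes can show.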

Other observations

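The genes and the reduced list below were picked after their values were seen. Among called genes outside the fixed lists, the 3 butyrophilin genes BTN3A3, BTN3A2 and BTN3A1, which encode surface proteins recognised by gamma delta T cells, were 2.67-fold, 2.48-fold and 2.04-fold lower with 7l (limma adjusted p = 0.0257, 0.0108 and 0.0269). They are close paralogs, so shared signal leaves their separate values uncertain. GBP5, EPSTI1 and the immunoproteasome gene PSMB8, known to be induced by interferon, were 1.73-fold, 1.61-fold and 1.41-fold lower. Of genes with roles in chromosome segregation or cytokinesis outside the mitosis list, 4 picked for their calls were higher, with no test of such genes as a group: CEP55 by 0.70 ± 0.07, SGO1 by 0.71 ± 0.08, HJURP by 0.66 ± 0.08 and KIFC1 by 0.58 ± 0.07 on the log2 scale (± SE).

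MAFG, whose product pairs with NRF2 on DNA, was 2.37-fold higher (limma adjusted p = 0.0230). A probe for the ferritin pseudogene FTH1P3 was 3.91-fold higher (adjusted p = 0.00295), and signal shared with its parent gene leaves the source uncertain. Without SLC7A11, the 1 tested gene it shares with the NRF2 list, the ATF4 and amino acid list had a median of 0.47. Over the alternatives its medians were 0.38 to 0.51. Leaving out 1 gene could move the median only a little.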
